A study of Danio rerio with 4 samples.

How the data were processed

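RNA of whole zebrafish embryos (Danio rerio, strain AB) between 90% epiboly and tailbud, the end of gastrulation, was sequenced in 4 libraries. The 2 genotypes were m39, a deletion allele of the cloche locus, and WT. The labels call the WT libraries wildtype, and the title of the series calls the controls siblings. Each genotype had 1 poly(A)+ library, made from RNA with a poly(A) tail, and 1 total RNA library, so each of the 4 groups held 1 library. Per the labels' design text, RNA was extracted from single embryos and then pooled by genotype. Whether the poly(A)+ and total RNA libraries came from the same pools is not given in the sources used here. Groups were taken from the labels.

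The authors aligned and assembled the reads against GRCz10 with tools that the submitters' processing notes name without a role or order: TopHat2 2.0.13, Bowtie2 2.2.3.0, Cufflinks 2.2.1 and bedtools 2.21.0. Filters, the strand setting and the handling of reads with several matches are not given in the sources used here. The deposited expression signal is, per the file headers, in RPM (reads scaled to library size) for each merged Cufflinks locus, in 1 table per library type. The columns summed to more than the nominal RPM total (1023266 in the WT poly(A)+ library and 1035573 in the WT total RNA library), so the values were treated as a signal relative to a library total that the authors chose. In each column 100% of the values were whole multiples, within 0.001 reads, of the worth of 1 read, and this returned whole reads. The totals used by the authors came to 30847616 reads for WT poly(A)+, 29261473 for m39 poly(A)+, 27968546 for WT total RNA and 26473537 for m39 total RNA. Reads over loci summed to 31565304, 29937013, 28963462 and 27410617 in the same order, more than these totals. Whether some reads were counted in more than 1 locus or the totals left some reads out was not tested.

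Loci without a gene name held 1.03% and 1.02% of the reads in the WT and m39 poly(A)+ libraries and 3.22% and 3.14% in the WT and m39 total RNA libraries. They were left out of scaling and of gene tests and were used for the search for absent loci, in which unnamed loci within 500 bases of each other were joined. Gene positions came from the exons of the deposited gene models on GRCz10, since the locus column merges overlapping genes. Genes were matched between the tables by name, chromosome and strand, with overlapping spans, which gave 29728 genes. Of these, 84.0% had the same coordinates in both tables. Without a known strand setting, reads of a gene and of a gene on the opposite strand cannot be told apart, and near-identical gene copies may share reads. Another table held 18 columns of a human exon array, matched no sample of these libraries and was not used here.

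Within each library type, log2 folds of m39 over WT were computed on TMM-scaled RPM with a pseudocount of 0.5 reads, which understates the change of genes with few reads. With 1 library per group there was no replicate check and no p-value. Each ratio has an exact (Clopper-Pearson) 95% interval that covers counting error only, and reads are not independent molecules. A gene passed the size rule with at least 20 reads in the higher library and at least a 2-fold difference. Counting noise was gauged by 100 random splits of each gene's reads. A fold against 0 reads is a lower bound against a floor of 3 reads per library.

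The 4 libraries were also fitted together with library type and genotype as terms, which leaves 1 residual degree of freedom. The test was limma with a variance trend on log2(TMM-scaled RPM + a pseudocount of 0.5 reads), after filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. It sets the genotype difference against a spread estimated from its disagreement between the library types, which may be technical. With 17.5 prior degrees of freedom against 1 residual, limma took each gene's spread mostly from the trend across genes. A small p-value therefore does not mean that the library types agreed closely for that gene. The plan had named edgeR's quasi-likelihood test. The deposited unit was not counts, so limma took its place and edgeR on the recovered reads became an alternative. Apart from this exchange, the comparisons, thresholds, gene lists and the rule for named genes were fixed before the data were examined.

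The fits were tested on simulated data, with counts drawn for the real genes at the estimated dispersion and 200 changed genes per draw. That dispersion came from these 4 libraries, so variation between pools of the same genotype was not simulated, and the false-call rates leave it out. With limma 4.74% of unchanged simulated genes had an unadjusted p under 0.05, against 1624 of 20321 genes in the real fit, which may include changed genes. In the first of 6 draws, 20.9% of limma's calls were false, and 5 more draws were added after that value was seen. Over the 6 draws, on 20485 to 20550 genes, limma made 866 calls, of which 54 were false (6.24%, from 0 to 20.9% in single draws), and 29 of the false calls were of genes with fewer than 20 reads in the libraries of 1 type. It recovered 43.7% of the genes changed by 0.5 on the log2 scale, 72.1% of those changed by 1 and 95.8% of those changed by 2. A limma fit with a weight per value (vooma) gave 3.07% false calls, edgeR 4.43% and DESeq2 0%. Limma with 1 variance per gene stayed the main test, because the calls in the real libraries were already known, and the weighted fit was added as an alternative. In simulated counts of 15802 genes the size rule in both library types recovered 93.9% of genes changed by 1.5 on the log2 scale and called 0 unchanged genes.

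Loci absent from m39 had at least 20 WT reads and at most 3 m39 reads over both library types together. Their number on chromosome 13 was compared with 10000 random placements among expressed loci (permutation, one-sided). Fisher's exact test, two-sided, compared each chromosome with the others, with Benjamini-Hochberg adjustment over chromosomes. The end of chromosome 13 from LOC100331306 onwards, called the terminal interval here, was delimited after its values were seen. For each of the 22 gene lists, the median log2 fold was placed among the medians of 10000 random lists of the same size matched on expression, as a description of these libraries. Members needed 20 reads in the higher library of both types. The lists covered blood and endothelial precursors, lateral plate, paraxial and axial mesoderm, endoderm, neural ectoderm, neural crest, epidermis, the yolk syncytial layer and germ cells. Others covered apoptosis, heat shock, the cell cycle, later and earlier stages, Hox genes, BMP and Nodal signalling, and FGF, Wnt, Notch and retinoic acid signalling. The remaining lists held bHLH-PAS factors with hypoxia targets, histones and small RNAs chosen by symbol as RNAs without poly(A) tails, mitochondrially encoded genes and ribosomal proteins.

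The rule for named genes took up to 12 genes each way that met the size rule in both library types, up to 10 absent loci, up to 4 members per list, the blood and endothelial regulators tal1, lmo2, etv2, gata1a, fli1a, spi1b and drl, and 5 genes each way between the library types. The calls of the 4-library fit were named in addition, chosen after their values were seen. A RefSeq gene table of assembly GRCz12tu served for gene order and synonyms only. Alternatives covered the scaling, the pseudocount, the read minimum, the fold, the model terms, the test, the use of chromosome 13 and the matching of random lists. Tool versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.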

Results

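Whole-embryo RNA was measured in 4 libraries, 1 for each combination of genotype (m39 or WT) and library type (poly(A)+ or total RNA). The sum of reads over loci was 31565304 in the WT poly(A)+ library, 29937013 in the m39 poly(A)+ library, 28963462 in the WT total RNA library and 27410617 in the m39 total RNA library. A count of 0 allowed up to 0.0973 RPM in the WT poly(A)+ library, 0.103 in the m39 poly(A)+ library, 0.107 in the WT total RNA library and 0.113 in the m39 total RNA library. There were no replicates within a group, and intervals and limits cover counting error only. Cloche mutants lack nearly all blood and endothelial cells, and the stated aim of the design was to isolate the cloche gene from RNA lost in the m39 deletion.

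Neighbouring genes at the end of chromosome 13 (GRCz10) fell in m39. Of the 22 genes whose level differed between genotypes in the fit of all 4 libraries, 10 lay within the terminal interval, between base 51413973 and the last annotated base of the chromosome, 51778812, and all 10 fell in m39. The kinesin light chain gene klc1b (51518001 to 51530159) fell by 6.29 on the log2 scale (SE 0.226, limma adjusted p = 2.80e-12), from 846 reads to 9 in poly(A)+ RNA and from 594 to 7 in total RNA. The gene srfb, a serum response factor paralogue (51576705 to 51591146), fell by 5.60 (SE 0.466, limma adjusted p = 1.17e-06). The kelch domain gene klhdc3 (51769523 to 51778812), the last annotated gene of the chromosome, fell to 16 reads from 246 in poly(A)+ RNA and to 7 from 148 in total RNA (log2 -3.78 and -4.24, limma adjusted p = 1.60e-07).

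Other losses lay beside these genes. The mitochondrial ribosomal protein gene mrpl2, under its RefSeq symbol (51653169 to 51663014), fell by 4.26 on the log2 scale (limma adjusted p = 7.82e-12). The gene zgc:64043 (synonym tmem254; 51735363 to 51743451) fell by 2.77 (limma adjusted p = 3.69e-09), and zgc:66337 (synonym lbh; 51608719 to 51617458) fell by 2.56 (limma adjusted p = 1.95e-06). The acyltransferase gene lycat (synonym lclat1; 51747109 to 51754207) fell (log2 -0.86 and -1.55, limma adjusted p = 1.75e-05), and pwwp2b, at the start of the interval (51485145 to 51503836), fell by 0.83 (limma adjusted p = 1.66e-05). LOC101885379, which lies on the opposite strand within klc1b, had 57 poly(A)+ and 297 total RNA reads in WT and 0 in m39, at least 17.4-fold and 94.3-fold lower, and the receptor-like gene ptk7b had 20 and 13 reads in WT and 0 in m39, at least 6.11-fold and 4.13-fold lower. Both passed the fit (limma adjusted p = 8.42e-07 and 0.0199), but LOC101885379 was lost with DESeq2 and ptk7b with DESeq2, with the authors' totals and without a read filter.

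The share of WT signal that remained in m39 differed between genes of the interval. In poly(A)+ RNA klc1b kept 1.16% (95% interval 0.529 to 2.215), zgc:64043 kept 12.3% (9.81 to 15.2) and lycat kept 55.2% (50.8 to 60.04). The transporter gene slc30a10 (51757314 to 51764490), which lies between lycat and klhdc3, had 58 WT and 49 m39 poly(A)+ reads and 207 WT and 240 m39 total RNA reads, a share of 92.2% (61.7 to 137) and 122% (101 to 147). A model of LOC557305 without a strand kept 77.1% in poly(A)+ RNA (59.6 to 99.6), from 150 WT reads, while its plus-strand model had 27 WT reads and 0 m39 reads over both types. A locus without a gene name on the unplaced contig GRCZ10_NA449 (21774 to 25171) had 493 WT and 2 m39 poly(A)+ reads, a share of 0.443% (0.0535 to 1.61). In total RNA the joined locus had 342 WT reads and 1 m39 read. The named gene of the same contig, LOC100329773, had 187 WT and 215 m39 poly(A)+ reads and 42 WT and 36 m39 total RNA reads. Reads from copies elsewhere in the genome could not be separated, and no genome sequence was searched.

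Over the genome, 12 loci were absent from m39, and 7 of them lay on chromosome 13, all within the terminal interval. They were LOC100331306, LOC101885379, ptk7b, the plus-strand model of LOC557305 and 3 loci without a gene name. No more than 4 fell on chromosome 13 in 10000 random placements among 22424 expressed loci (one-sided permutation p = 1e-04, the smallest the placements can give), and 801 expressed loci lay on it. The placements treated loci as independent, although the 7 lay within 1 interval. Of the others, 1 was the locus on the unplaced contig and 4 lay elsewhere, among them socs4 on chromosome 17. It had 20 WT and 0 m39 reads in total RNA but 1 WT and 2 m39 reads in poly(A)+ RNA. With a minimum of 50 WT reads and at most 5 m39 reads, 3 of 4 absent loci lay on chromosome 13, with at least 10 WT reads and 0 m39 reads 9 of 63, with poly(A)+ libraries alone 4 of 5 and with total RNA libraries alone 7 of 15.

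**Figure D1:**
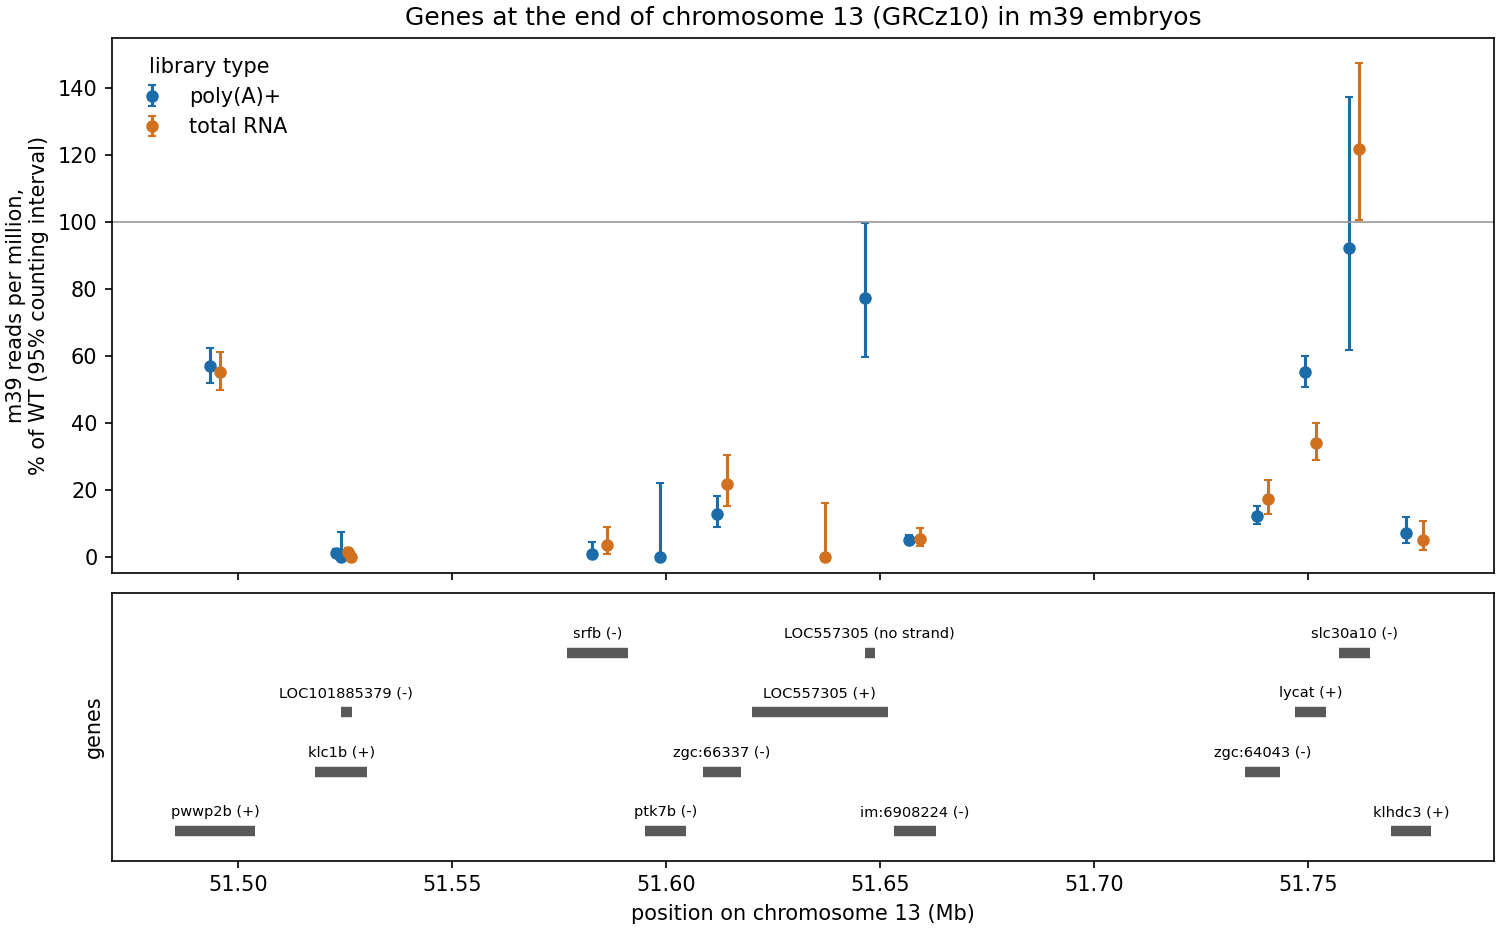
m39 signal (RPM) as a percentage of WT, with 95% counting intervals, against position on chromosome 13 for named loci from pwwp2b onwards with at least 20 WT reads, in the poly(A)+ pair (blue) and the total RNA pair (orange), above a map of the genes with their strands (mrpl2 under its older im: name). The poly(A)+ share was 1.16% for klc1b, 55.2% for lycat and 92.2% for slc30a10.

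Chromosome 13 also held more of the genotype differences than its number of genes would give. It carried 12 of the 22 genes that passed the fit, against 729 of the 20321 tested (Fisher's exact test, two-sided, odds ratio 32.8, adjusted p over chromosomes = 4.83e-11). The test treats genes as independent, although 10 of the 12 lay within the terminal interval, so its p-values describe these libraries only. It carried 8 of the 17 genes that met the size rule in both library types, against 584 of 15969 (odds ratio 23.7, adjusted p = 1.38e-06). With log2 folds of at least 0.5 in both types it carried 21 of 207 genes (odds ratio 3.05, adjusted p = 6.04e-04), and without the terminal interval 12 of 198 (odds ratio 1.74, adjusted p = 0.816). Without the terminal interval 1 of 10 genes that met the size rule lay on the chromosome (odds ratio 2.98, adjusted p = 1). For the calls of the fit, 2 of 12 remained outside the interval (odds ratio 5.48, adjusted p = 0.812).

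Both of these calls lay at lower coordinates than the interval. The nucleoside transporter gene slc29a1a (46541754 to 46627239) rose by 0.42 on the log2 scale (SE 0.0567, limma adjusted p = 9.78e-04). The kinase gene eif2ak2, a sensor of double-stranded RNA (49894704 to 49920857), fell from 13 reads to 0 in poly(A)+ RNA and from 79 to 14 in total RNA (ratio 0.186, 95% interval 0.0973 to 0.331; limma adjusted p = 0.0193), and its fitted fold depends on the pseudocount. Neither call was kept with the authors' totals, and that of eif2ak2 was also lost with DESeq2 and without a read filter.

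Off chromosome 13, 5 genes rose and 5 fell in m39 in the fit of all 4 libraries, all with the same sign in both library types. The keratin gene krt91 (chromosome 19, 5462077 to 5464210) fell by 0.71 on the log2 scale (SE 0.0733, limma adjusted p = 2.42e-05), from 5312 reads to 2658 in poly(A)+ RNA and from 2302 to 1487 in total RNA. LOC100331968 (chromosome 17) rose by 0.63 on the log2 scale (SE 0.0678, limma adjusted p = 4.36e-05). The forkhead factor gene foxo3b (chromosome 20) fell by 0.84 (SE 0.142, limma adjusted p = 0.0137), and the pyruvate carboxylase gene pcxb (chromosome 7) fell by 0.53 (limma adjusted p = 0.0249). The genes si:ch211-113a14.16 (0.60), si:dkeyp-67e6.5 (0.68) and si:dkey-29b22.6 (0.50) rose, and zgc:194878 (-0.82) and si:dkey-204l11.1 (-0.84) fell. The fit weighs both library types alike, whatever their reads. For zgc:194878 there were 27 WT and 11 m39 poly(A)+ reads (log2 -1.14) but 10917 and 7221 total RNA reads (-0.53). For si:ch211-113a14.16 there were 59 WT and 86 m39 poly(A)+ reads (0.67) and 6798 and 9235 total RNA reads (0.51).

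The fit called 22 of 20321 genes, 6 higher and 16 lower in m39, and 1624 genes had an unadjusted p under 0.05. Of the 10 calls off chromosome 13, those of krt91 and LOC100331968 were lost only when the term for library type was left out, a setting in which the fit made 0 calls (9 genes at an unadjusted p under 0.05). A further 7 were also lost with the authors' totals, and of these all but si:ch211-113a14.16 with DESeq2 and without a read filter. The calls of pcxb, si:dkey-204l11.1 and si:dkey-29b22.6 were also lost when chromosome 13 was left out of the fit. The number of calls ranged from 0 to 85 over the alternatives.

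Within each library type, many more genes met the size rule than counting noise gave, and few did so in both. In poly(A)+ RNA 89 genes were higher and 197 lower in m39 among 17320 tested, against at most 55 and 65 in random splits. In total RNA 206 were higher and 288 lower among 19281, against at most 58 and 71. In both types together 6 were higher and 11 lower among 15969 genes, and independent lists would share 0.299 and 1.19. The overlap includes genes of the terminal interval, and without it 10 of the 17 genes remained. The numbers for independent lists treat all genes alike, although genes with few reads meet the rule more easily. Across genes, which are not independent replicates, the log2 folds of the library types had a Pearson correlation of 0.208 and a Spearman correlation of 0.117. Both include the genes of the terminal interval. Among 5432 genes with many reads outside it, the Pearson correlation was 0.197 and the Spearman correlation 0.176. The poly(A)+ pool and the total RNA pool may hold the same embryos, so the overlap does not stand for separate embryos.

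Outside the interval the genes lower in both types included rspo1, a secreted activator of Wnt signalling, with 24 WT and 5 m39 poly(A)+ reads and 32 WT and 7 m39 total RNA reads (log2 -2.04 and -2.05). The parathyroid and pharyngeal factor gene gcm2 had 25 WT and 6 m39 poly(A)+ reads and 23 WT and 3 m39 total RNA reads. LOC101883737 (log2 -1.60 and -2.20) and LOC799225 (log2 -1.01 and -1.31) completed the lower group. The higher group included the zinc finger gene zbtb32 (log2 1.71 and 1.72), sb:cb54 (1.48 and 1.60), card14 (1.01 and 1.68), wdr78 (1.04 and 2.54) and LOC100535903 (1.16 and 1.31). None of the genes named here passed the fit with limma, and apart from card14 they had at most 57 reads in any library.

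**Figure D2:**
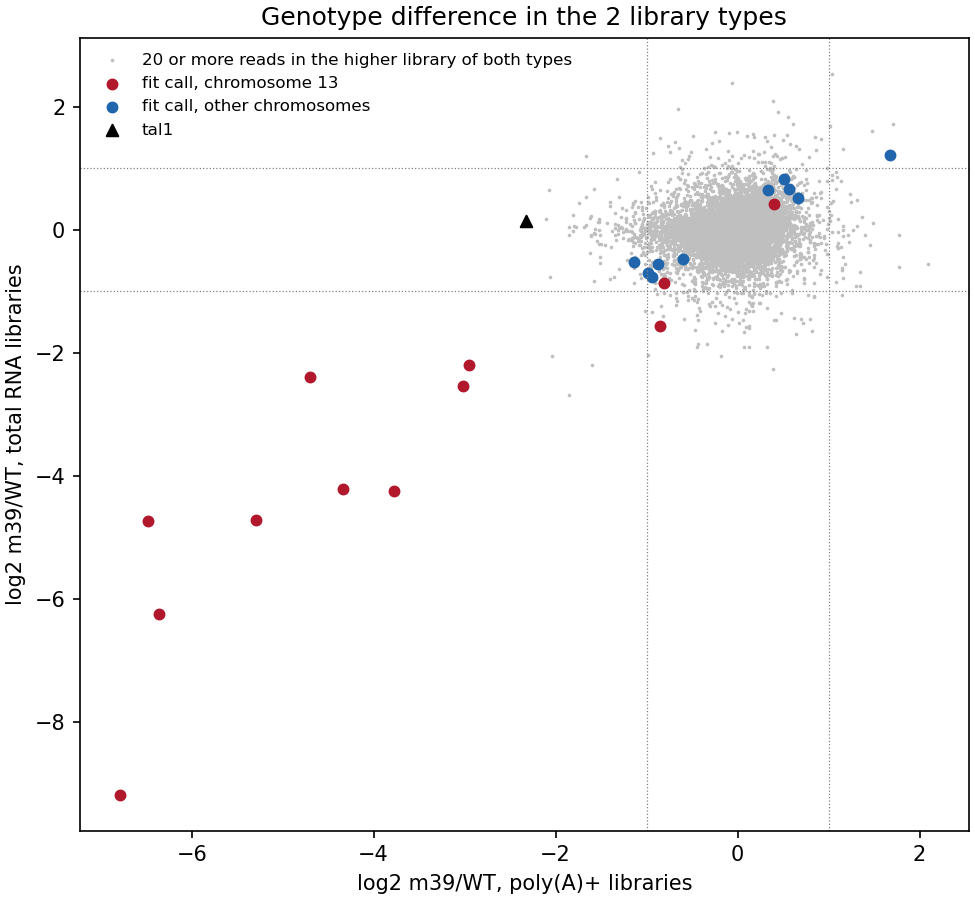
Log2 fold of m39 over WT in total RNA against that in poly(A)+ RNA, 1 point per gene, with the calls of the 4-library fit on chromosome 13 in red and on other chromosomes in blue, tal1 as a triangle, and dotted lines at a 2-fold difference. The point at the lower left is LOC101885379, with 0 m39 reads, and across the 15969 genes in grey the Pearson correlation was 0.208.

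Blood and endothelial regulators, the lineages that cloche mutants lack, did not pass the fit at this stage. The endothelial ETS factor gene etv2 had 48 WT and 17 m39 poly(A)+ reads and 16 WT and 5 m39 total RNA reads, ratios of 0.387 (95% interval 0.208 to 0.684) and 0.328 (0.0940 to 0.938), with a fitted log2 of -1.42 (SE 0.437, limma adjusted p = 0.425). The blood factor gene tal1 had 24 WT and 4 m39 poly(A)+ reads and 17 WT and 18 m39 total RNA reads (fitted log2 -1.08, limma adjusted p = 0.654), ratios of 0.182 (0.0459 to 0.530) and 1.11 (0.541 to 2.30). The log2 folds in poly(A)+ and total RNA were 0.25 and 0.07 for lmo2, -0.23 and -0.81 for fli1a, -0.12 and -0.26 for spi1b and 0.03 and 0.05 for drl. The erythroid factor gene gata1a had 2 WT and 4 m39 poly(A)+ reads and 4 WT and 12 m39 total RNA reads, too few for the fit. Of 34 list members tested, 0 passed over all genes and 0 passed when adjusted over the list alone, with 4 at an unadjusted p under 0.05. The median log2 fold of the 27 expressed members was 0.09 in poly(A)+ RNA (percentile 97.5 among matched random lists) and 0.07 in total RNA (percentile 91.7), and examples were spi1a (0.48 and 0.29) and flt4 (0.30 and 0.23). The expressed members did not include etv2 and tal1, which had fewer than 20 reads in total RNA. The poly(A)+ median lay inside the central 95% against unmatched lists (percentile 97.47), with at least 50 reads (percentile 96.1) and against lists matched on the ratio of total to poly(A)+ reads (percentile 96.7).

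The apoptosis list, of damage response and cell death genes, was the only list with a member called over all genes, foxo3b. Adjusted over the list alone, 5 of 24 tested members fell and 0 rose in m39 with limma (smallest adjusted p over the list alone = 2.75e-04). These were foxo3b, the death effector gene bbc3 (puma; log2 -0.97 in poly(A)+ and -0.49 in total RNA), the caspase gene casp8 (-0.69 and -0.84), mdm2 (1525 WT and 1109 m39 poly(A)+ reads), and phlda3 (219 WT and 147 m39 poly(A)+ reads). The list median was -0.11 in poly(A)+ RNA (percentile 0.0700) and -0.07 in total RNA (percentile 0.960), while the cell cycle inhibitor gene cdkn1a had log2 folds of -0.08 and -0.08. Against random lists not matched on expression, the total RNA median had percentile 3.44.

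Ribosomal protein genes stood higher in the m39 poly(A)+ library as a group. The median log2 fold of 85 expressed members was 0.16 in poly(A)+ RNA (percentile 100 among matched random lists) and 0.04 in total RNA (percentile 99.8). Of 89 tested members 0 passed over all genes, and 14 rose when adjusted over the list alone with limma (smallest adjusted p over the list alone = 0.0359), among them rpl38 (log2 0.20 and 0.20) and rplp1 (0.17 and 0.18). The symbol pattern also caught rps6k kinase genes, such as rps6ka3a (-0.31 and -0.20). In total RNA the percentile was 96.4 against unmatched lists and 91.0 against lists also matched on the ratio of total to poly(A)+ reads. In poly(A)+ RNA the percentile against ratio-matched lists was 99.98. The ribosomal list had a low ratio (median log2 of total over poly(A)+ -2.23). The tenth of all genes with the lowest ratio had a median poly(A)+ log2 fold of 0.13, so much of the poly(A)+ rise was shared with such genes.

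Later stage markers lay outside the central 95% of random lists in total RNA, and the difference between the library types was not tested. Their list had a median log2 fold of -0.02 in poly(A)+ RNA (percentile 36.8) and -0.17 in total RNA (percentile 0.180), and the muscle actin gene acta1a, with 329 WT and 170 m39 poly(A)+ reads and 131 WT and 73 m39 total RNA reads, fell when adjusted over the list alone (over all genes, limma adjusted p = 0.0964). Earlier stage markers had medians of 0.08 (percentile 94.5) and 0.04 (percentile 91.7). Hox genes had medians of -0.10 (percentile 5.62) and -0.08 (percentile 4.83), with hoxd9a at -0.28 and -0.50, and lay outside the central 95% in poly(A)+ RNA against lists matched on the ratio of total to poly(A)+ reads (percentile 0.665) and in total RNA against unmatched lists (percentile 1.68). The cell cycle list had medians of 0.03 (percentile 33.1) and 0.03 (percentile 86.5), and heat shock genes had 0.03 (percentile 50.4) and -0.04 (percentile 2.88; 2.45 with at least 50 reads and 2.33 against ratio-matched lists, outside the central 95%). In the last 4 of these lists 0 members passed over all genes or when adjusted over the list alone.

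Germ layer and tissue lists held 0 calls over all genes. Lateral plate and cardiac mesoderm had median log2 folds of 0.04 in poly(A)+ RNA (percentile 77.2) and -0.01 in total RNA (percentile 36.6). Paraxial mesoderm had 0.06 (percentile 86.8) and -0.03 (percentile 3.92), and axial mesoderm 0.06 (percentile 86.2) and 0.06 (percentile 92.7). Endoderm had 0.04 (percentile 62.2) and 0.07 (percentile 96.1), with the chemokine receptor gene cxcr4a (log2 0.26 and 0.26) higher when adjusted over the list alone. Neural ectoderm had 0.05 (percentile 81.3) and 0.04 (percentile 91.9), and neural crest -0.01 (percentile 18.7) and 0.03 (percentile 81.7). Epidermis had 0.02 (percentile 24.4) and -0.01 (percentile 8.94), with evplb (-0.24 and -0.17) lower when adjusted over the list alone. The yolk syncytial layer had 0.06 (percentile 70.2) and 0.00 (percentile 32.1), with apoa4a higher when adjusted over the list alone (10 WT and 21 m39 poly(A)+ reads, 0 WT and 14 m39 total RNA reads). The germ cell list had 0.15 (percentile 98.7) and -0.01 (percentile 47.1), with hook2 (0.45 and 0.37) higher when adjusted over the list alone.

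Signalling lists held 0 calls over all genes and 0 when adjusted over the list alone. BMP and Nodal signalling had median log2 folds of 0.07 in poly(A)+ RNA (percentile 92.8) and 0.04 in total RNA (percentile 89.0), with admp at 0.18 and 0.36. FGF, Wnt, Notch and retinoic acid signalling had 0.02 (percentile 35.6) and 0.02 (percentile 67.1). The bHLH-PAS and hypoxia list, the class of transcription factor to which the gene at cloche belongs, had -0.17 (percentile 0.170) and 0.03 (percentile 73.1). With at least 50 reads its poly(A)+ median was -0.10 (percentile 6.27), inside the central 95%. The histone and small RNA list, chosen by symbol for RNAs without poly(A) tails, had 0.02 (percentile 49.0) and 0.06 (percentile 96.7). Its members were not all of that kind, as 4 of 10 were at least 2-fold higher in poly(A)+ RNA than in total RNA and their median log2 of total over poly(A)+ was -0.76. The histone genes hist1h4l (0.66 and 0.22) and histh1l (0.23 and 0.12) were higher and h2afy2 (-0.13 and -0.22) was lower in m39 when adjusted over the list alone. The list of mitochondrially encoded genes matched 0 symbols. With the authors' totals the poly(A)+ medians of the lateral plate, endoderm, neural ectoderm, epidermis, heat shock, cell cycle, FGF and histone lists turned negative, and the total RNA medians of the lateral plate and germ cell lists turned positive. That scaling shifts the folds of a pair by nearly a constant, and it left the same lists outside the central 95%.

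**Figure D3:**
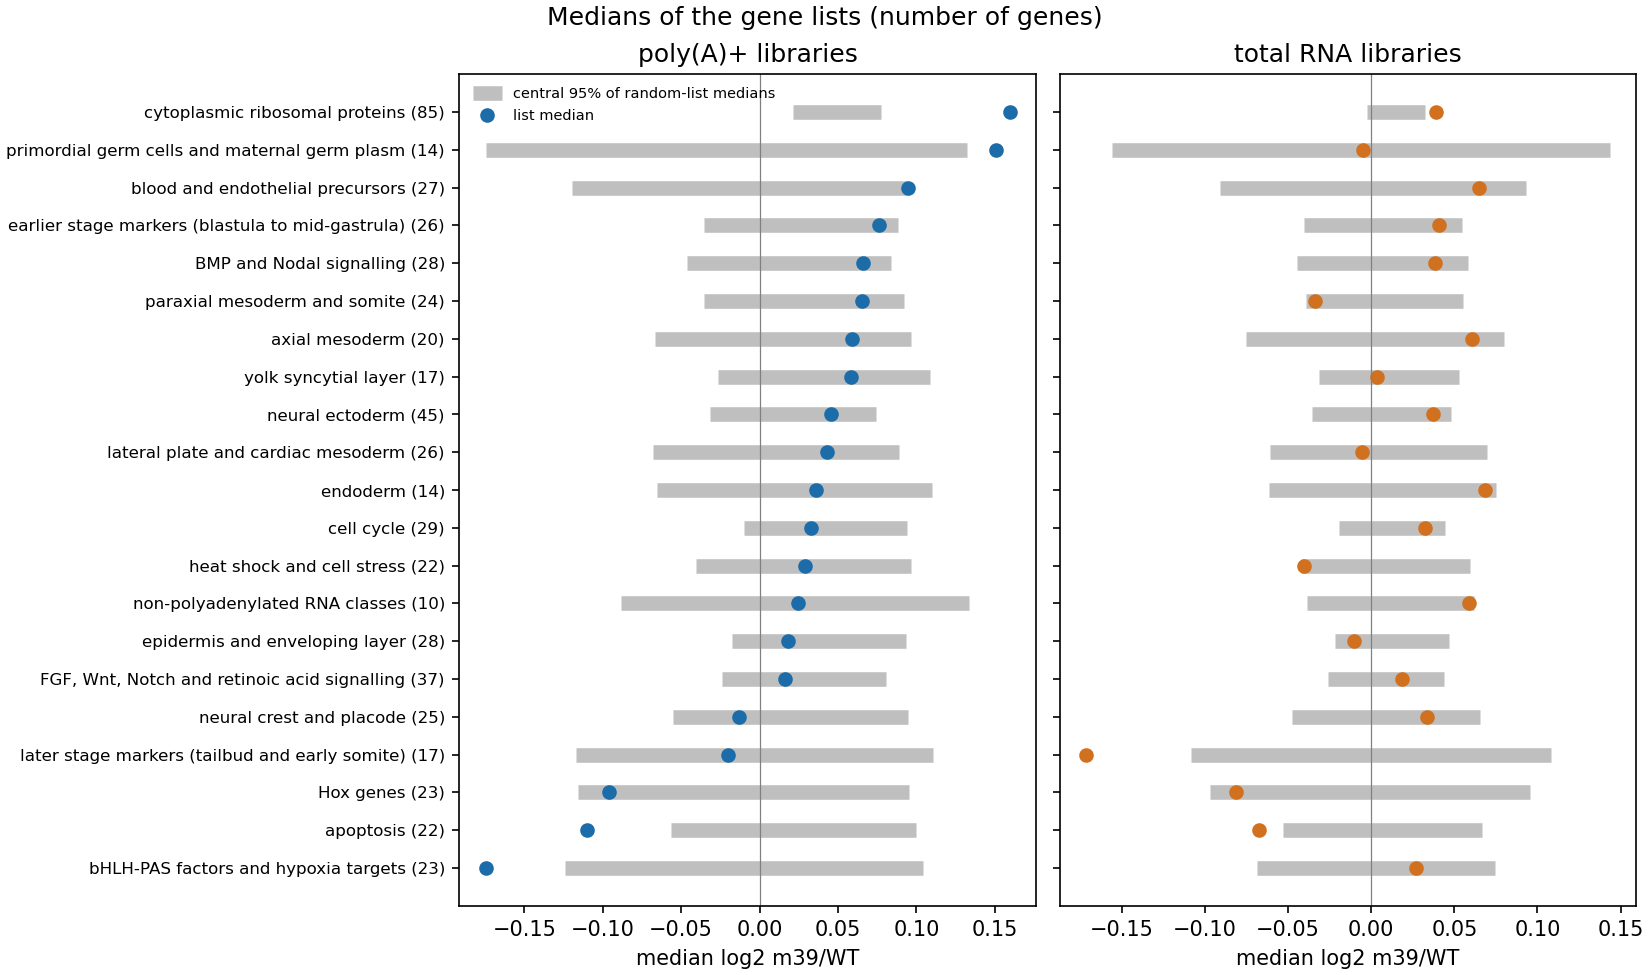
Median log2 fold of m39 over WT for each gene list in poly(A)+ and total RNA, with the central 95% of medians of matched random lists as bars. In poly(A)+ RNA 5 lists and in total RNA 3 lists lie outside their bars.

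At least 2-fold differences were far more numerous between library types than between genotypes. Matched genes over the median expression were ranked by this difference. Those with the largest excess in total RNA were rn7sk, the 7SK RNA (log2 total over poly(A)+ 9.84), zgc:153409 (9.51), the RNase P RNA gene rpph1 (9.38), LOC103908712 (9.12) and LOC101884632 (9.02). The mitochondrial ribosomal RNA genes rnr1 and rnr2 were not in that ranking. Together they held 9.50% of reads in the WT and 8.70% in the m39 total RNA library. In both poly(A)+ libraries 0% of reads stood under these names. Gene models without these names would give the same value, so it does not show that this RNA was absent. The genes ccdc113 (-6.52), acot13 (-6.15), col17a1a (-5.03), LOC101885550 (-3.86) and spata1 (-3.33) were higher in poly(A)+ RNA. Ribosomal protein genes had a median of -2.23, with 79 of 87 at least 2-fold higher in poly(A)+ RNA, while bHLH-PAS factors and hypoxia targets had 0.33, with 11 of 28 at least 2-fold higher in total RNA. Of 19008 genes, 4615 were at least 2-fold higher in total RNA and 3593 in poly(A)+ RNA, and across genes the difference had a Pearson correlation of 0.934 between the genotypes. Gene models differed between the deposited tables for some genes, so these are values without a test, and all 5 genes named as higher in poly(A)+ RNA had shorter exon models in the total RNA table.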

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

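The test of the apoptosis list against ratio-matched random lists was set before its value was seen, and the tests of the other explanations in this part were chosen only after the result was seen. The gene tal1 had opposite signs in the library types, with a log2 fold of -2.33 in poly(A)+ RNA (ratio 0.182, 95% counting interval 0.0459 to 0.530) and 0.15 in total RNA (ratio 1.11, interval 0.541 to 2.30), and it was 1 of 115 named genes examined in this way. The intervals did not overlap, but the difference between the library types was not tested.

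Genes lower in the m39 poly(A)+ library (197, of which 163 were expressed in both library types) were often rich in total RNA relative to poly(A)+ RNA: of the 156 of these 163 outside the terminal interval, 59.0% were in the tenth of genes with the highest ratio. Counting noise gave at most 65 lower genes in 100 random splits, and with exon length held fixed the rank correlation of the fold with the ratio across 11527 genes was still -0.359, which argues against noise or length alone. In total RNA the same 156 genes had a median log2 fold of -0.0129, which argues against a lower amount of these RNAs in m39 embryos as a set. A difference between the poly(A)+ libraries in how much RNA poor in poly(A) they carried may account for the pattern: among genes with at least 100 reads, the tenth with the highest ratio had a median poly(A)+ fold of -0.196, against 0.0309 in the other genes and -0.000615 in total RNA, and without that minimum the tenth had -0.280 and -0.0111. With a ratio from WT libraries alone that median was -0.176, and a difference in poly(A) tails between genotypes remained open and untested.

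Residual m39 reads over the terminal interval differed from gene to gene. RNA of siblings in the m39 pool would leave each deleted gene the same share, but the lower bound for lycat was 50.8% and the upper bound for klc1b 2.215%, which argues against such RNA as the only source. In the later gene order 0 of the genes lycat and slc30a10 lay outside the stretch from pwwp2b to klhdc3, which argues against a build that placed them in this stretch by error, although the order of genes within it differs between the assemblies. Reads of near-identical copies elsewhere could account for the 2 genes from klc1b onwards with at least 100 WT reads that kept over 30% in total RNA (lycat and slc30a10), and this cannot be told apart from their own transcription because no sequence was searched. Their retention in the m39 genome also remained open and untested.

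The lower apoptosis list was not an effect of the poly(A)+ trend alone: against random lists matched on the ratio its poly(A)+ median had percentile 0. A stage difference between the pools could contribute and cannot be told apart, since later markers had percentile 36.8 in poly(A)+ RNA and 0.180 in total RNA. The genotype, with 1 pool each, remained open and untested.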

How the results depend on the processing

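The edgeR test with TMM was the main test of the plan, and its use on recovered reads as an alternative was settled after seeing the data. Limma with the authors' totals, with median-of-ratios scaling, with a pseudocount of 5 reads or with a weight per value, the removal of the ratio trend, the terminal interval left out and lists matched on the ratio, with the authors' totals or without rps6k kinases were chosen after seeing the data. Against 22 calls, the fit made 12 with the authors' totals (2 higher, 10 lower), 85 with a pseudocount of 5 reads, 14 without a filter, 45 with at least 50 reads, 0 without library type, 7 without chromosome 13 (4 higher, 3 lower), 74 with edgeR, 44 with edgeR and median-of-ratios scaling, 13 with DESeq2, 85 with the trend removed (44 higher, 41 lower) and 63 with weights. All 22 were shared with the pseudocount, both edgeR, weighted and trend settings, and 11 were lost only without library type. The size rule gave, for poly(A)+ (286), total RNA (494) and both (17), 56, 75 and 8 genes with at least 50 reads, 1621, 2550 and 205 with at least 5 reads, and 19, 41 and 8 with at least 4-fold. A pseudocount of 5 reads gave 135 and 274 in the separate types, and without chromosome 13 both types shared 9. Higher minimums, 4-fold and fewer chromosomes lower these counts by construction, and elsewhere the cause was not tested. With the trend removed the poly(A)+ split was 112 higher and 126 lower, against 89 and 197. With the authors' totals both types shared 4 higher and 12 lower, and the library types differed in 5490 genes higher in total RNA and 2303 in poly(A)+ RNA, against 4615 and 3593. Absent loci on chromosome 13 numbered 3 with at least 50 WT reads and 4 in poly(A)+ libraries alone, against 7, and the odds ratio of the chromosome was 2.98 without the terminal interval. With at least 50 reads 3 poly(A)+ lists lay outside the central 95%, against 5. Of the values of named genes, 328 poly(A)+ folds kept within their interval and 11 moved, and 332 total RNA folds kept and 1 moved. Of fitted values 199 kept their call and 52 lost it, and no sign changed under these settings. No library could be left out within a group, and depth limited single calls, as random splits of the reads still gave up to 65 lower poly(A)+ genes.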

Other observations

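The tests in this part were chosen only after the result was seen. On chromosome 13 beyond 40 megabases but outside the terminal interval, 4 of 94 genes (4.26%) had log2 folds of at least 0.5 with the same sign in both library types, against 186 of 15385 (1.21%) on other chromosomes (Fisher's exact test, two-sided, p = 0.0285, not corrected for the choice of region). They were LOC101886519 (log2 -0.80 in poly(A)+ RNA and -0.74 in total RNA), LOC103912040 (-0.57 and -0.64), sb:cb54 (1.48 and 1.60) and LOC101882292 (1.09 and 0.86). The test treats genes as independent, although LOC103912040, sb:cb54 and LOC101882292 lay near each other (48452180 to 48741141). On the first 40 megabases 8 of 480 genes did so (1.67%, the same exact test, p = 0.392).

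The locus without a gene name on the contig GRCZ10_NA449 may belong to the deleted end of chromosome 13. LOC100329773, the named gene of the same contig, lay 3 places from klhdc3 in the later gene order, on chromosome 13, beside the end of the terminal interval. Between klhdc3 and LOC100329773 that table lists 2 genes. Only 1 of them is protein-coding, npas4l, a bHLH-PAS factor known as the cloche gene. Whether the locus is npas4l, the other gene listed there or another transcript of the contig cannot be told apart. Sequence and exons were not compared, and the deposited tables list no gene under the name npas4l.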
